A study of Bos taurus with 10 samples.

How the data were processed

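Bovine corpus luteum samples, 5 labelled MIX and 5 labelled ISe, were measured on single-colour Affymetrix whole-transcript arrays. Per the labels' protocols, pieces of tissue were snap-frozen, total RNA was extracted with TRIzol, and the samples were fragmented by enzyme and labelled with biotin using the WT Terminal Labeling Kit. The deposited values were taken as log2 signal per probeset, since they run from 0.54 to 14.17 with medians near 6.0 on every array, which the authors had processed before deposit. The programs GCOS 1.2 and Partek are named in the submitters' processing notes, with no role stated. The background correction, summarisation and normalisation are not given in the sources used here. The medians and quartiles of the 10 arrays are nearly equal, so the values were used as deposited, and no genome build was needed.

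Groups and replicate numbers came from the sample titles, and the labels give no batch, scan date or pairing. The value table holds 26773 probesets. The platform annotation given for this work pairs 18457 of them with 1 gene symbol, 688 with several and 7628 with none. The 19145 with at least 1 symbol (71.5%) were tested, and no gene was named from a probeset with several. Of the probesets with 1 symbol, 17996 had an Entrez identifier found in the current cattle gene table, which changed 0 symbols, and 1205 carried a placeholder name. For the 401 genes with more than 1 probeset, the probeset with the highest mean over the 10 arrays stood for the gene in gene lists.

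MIX was compared with ISe by a linear model per probeset with moderated variances (lmFit and eBayes of limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the 19145 probesets and a threshold of 0.05. Fold changes are MIX over ISe, errors of log2 differences are standard errors of the limma fit, and intervals are 95% intervals of that fit. The median standard error was 0.09 log2. On data simulated for this comparison with the 19145 probesets and 5 arrays per group, the fit recovered 70% of 50 changes of 0.5 log2, 96% of 50 changes of 1, 88% of 50 changes of -1 and 100% of 50 changes of 2, with 10 unchanged probesets among 187 calls. The simulated noise was independent between probesets, and the many planted changes eased the adjustment, so these rates can overstate what is found when few genes change. In the measured data FCGR1A, at a difference of 0.57 log2, had an adjusted p of 0.809. The distance between the groups was tested as the ratio of between-group to within-group sum of squares over all splits of the arrays into 5 and 5. For a single value, 5 against 5 arrays allow a smallest exact two-sided p of 0.00794.

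The test, the named-gene rule, the alternatives and 31 gene lists of cell types and pathways were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 31 lists. Genes were also adjusted over each list alone, which does not account for the number of lists examined. A list mean is the average over its genes of each array's value minus the gene's mean over the 10 arrays. Its difference was tested by exact permutation, adjusted over the lists, which was added after the data were examined. A single list at the smallest possible exact p would not pass this adjustment, so the adjusted exact test could hardly call a list. The rule named the 10 genes with the smallest unadjusted p in each direction where fewer passed the adjusted threshold, up to 4 genes with the smallest p in each list described, and a fixed set of luteal genes and every measured selenoprotein gene. FCGR2B, CCL2, VSIG4, HSD17B7, RRM1, PLIN1, ADIPOQ, GSDME, GNLY, BOLA, IFI47, NPS, LRRN3, CSRP3, FABP3 and SCD fall outside the rule and were chosen after their values were seen.

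Alternatives were quantile normalisation, centring on array medians, leaving out the dimmest 25% or 50% of probesets, all probesets of the table, 1 probeset per gene, trended and robust moderation, no moderation, array quality weights, averaging the probesets of a gene, and leaving out each array in turn. Leaving out MIX 1 and MIX 8 together, and counts of genes within lists under each setting, were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.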

Results

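Gene expression was measured in corpora lutea of cattle (Bos taurus), the glands that form from the ovulated follicle and secrete progesterone. The tissue was taken 7 days into the estrous cycle from cows given selenium in 1 of 2 forms, which the labels name only as ISe and MIX. Each group held 5 samples, and total RNA of each sample was hybridised to 1 whole-transcript array, so the number of arrays limits the precision. The labels do not say whether each sample came from a different cow, so the p-values measure the spread between these samples. The deposited values are on a log2 scale, with medians between 5.99 and 6.04 on the 10 arrays. The correlation between any 2 arrays lay between 0.980 and 0.990, and 0 pairs held identical values.

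The only comparison the design implies is MIX against ISe, which asks whether the form of selenium given to the cow is accompanied by a difference in luteal gene expression. Markers of macrophages and enzymes of cholesterol synthesis were higher in the MIX samples as groups of genes by camera with its preset correlation, but not with an estimated one (adjusted p = 0.263 and adjusted p = 0.347 with an estimated correlation). Genes of selenoproteins and of steroid hormone synthesis were not called as lists, with median log2 differences of 0.01 and -0.01. No single gene differed past the adjusted threshold: limma called 0 of 19145 probesets at an adjusted p under 0.05, with a smallest adjusted p of 0.809. At an unadjusted p under 0.05 there were 918 probesets, 512 higher and 406 lower in MIX, against 957.2 expected by chance, and a linear model without moderation gave 907 and 0 adjusted calls. Over all 19145 probesets the ratio of between-group to within-group sum of squares was 0.130, which 40 of all the splits of the arrays reached (exact permutation p = 0.317). Of 31 gene lists, camera with its preset correlation called 10, of which 7 were higher and 3 lower in MIX. It called 6 without MIX 1 and MIX 8 together, and 0 with an estimated correlation. Over splits of the arrays, the preset correlation gave a median of 6 called lists. Estimated correlations of the called lists ran from 0.014 (angiogenesis) to 0.685 (cell cycle), against the preset 0.01. They were 0.262 for macrophage markers and 0.279 for cholesterol synthesis. Where the estimate lies far above the preset, the preset p-values and the counts of genes in 1 direction overstate the evidence. MIX 8 stood apart on the first principal component at 32.8, with the other 9 arrays between -9.5 and 1.3, and MIX 1 on the second at -26.6.

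Macrophage and monocyte markers were higher in the corpora lutea of the MIX group by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.263). The exact permutation of the list means gave an adjusted p of 0.246, from a test that could hardly call a list. Of the 32 markers measured, 30 had a mean above that of ISe, with a median difference of 0.31 log2. FCGR1A, a high-affinity receptor for immunoglobulin G, averaged 6.33 ± 0.18 in MIX and 5.76 ± 0.13 in ISe (SD, n = 5 each), a 1.48-fold difference (adjusted p = 0.00329 over the list alone). CD68, a lysosomal glycoprotein of phagocytes, was 1.44-fold higher, CD14, the co-receptor for bacterial lipopolysaccharide, 1.42-fold, and C1QA, a chain of complement C1q, 1.43-fold. In all, 14 markers rose when adjusted over the list alone, by 1.22-fold to 1.56-fold (VSIG4, a complement receptor of tissue macrophages), 18 had an unadjusted p under 0.05 and 0 passed over all probesets. The 2 markers below ISe were FCGR2B at -0.20 ± 0.19 and CCL2 at -0.05 ± 0.29 (log2 difference ± SE).

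The mean of the macrophage list was higher than the highest ISe sample in 4 of the 5 MIX samples, and ISe 3 at 0.081 lay above MIX 11 at 0.055. The camera test with its preset correlation gave an adjusted p of 2.19e-18 over the 31 lists, against 0.263 with an estimated correlation. An exact permutation test of the list means, with a difference of 0.32 log2, gave p = 0.0159 before adjustment and 0.246 after it. A single list at the smallest possible exact p would not pass that adjustment either. The list median was 0.50 without the dimmer 50% of probesets. The count of 14 was 7 without ISe 7 or without MIX 10, 8 without ISe 2, without MIX 8 or in a linear model without moderation, and 3 without MIX 1 and MIX 8 together.

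**Figure D1:**
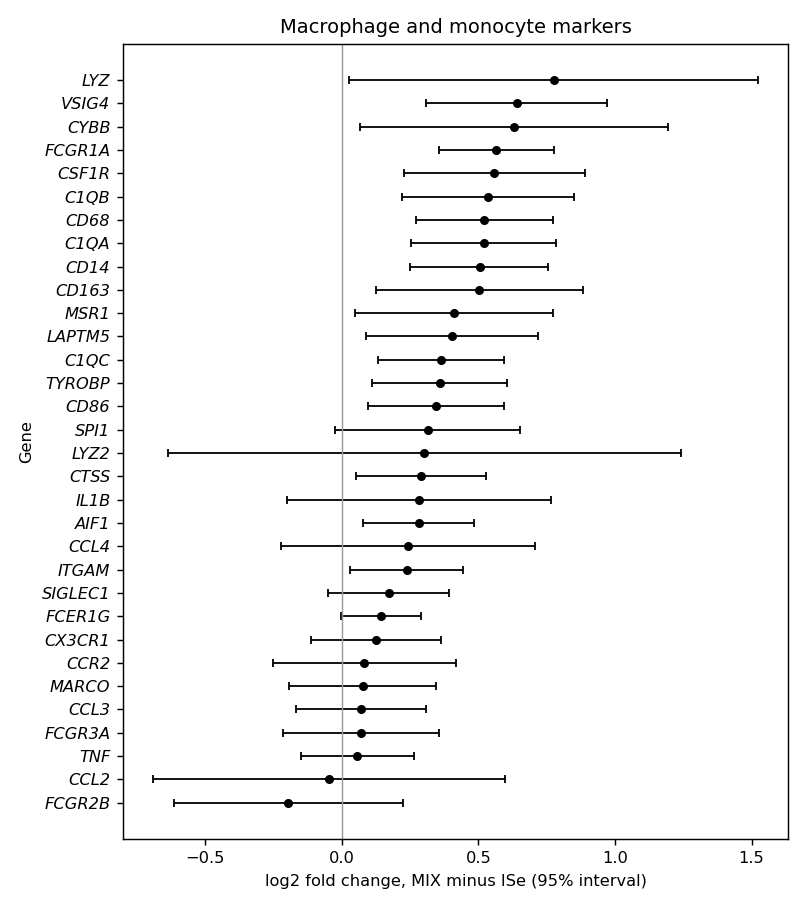
Log2 fold change of MIX over ISe (horizontal axis) for the 32 macrophage and monocyte markers measured (vertical axis), with points for the estimate from 5 arrays per group and bars for the 95% interval. The estimates of 30 markers lie above 0, and those of FCGR2B and CCL2 below it.

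Of the other immune lists, those of T and NK cells, antigen presentation and interferon-stimulated genes were also higher in MIX by camera with its preset correlation, and each had adjusted p = 0.571 with an estimated correlation. Markers of T and NK cells had a median difference of 0.16 log2 over 37 genes, led by NKG7, a granule protein of cytotoxic cells, at 0.48 ± 0.12 (log2 difference ± SE), and GZMA, a granzyme, at 0.86 ± 0.24, with CCL5 and EOMES next. GZMA averaged 4.38 in MIX and 3.52 in ISe, and EOMES 4.07 and 3.68, below the array medians near 6.0. The median level of the list, 5.23, also lay below them, so these differences are less certain. Antigen presentation genes had a median of 0.10 over 24 genes, with TAP1, which carries peptides to class I molecules, at 0.31 ± 0.08, B2M at 0.22 ± 0.08, CTSS at 0.29 ± 0.11 and BOLA-DMB at 0.30 ± 0.14. Interferon-stimulated genes had a median of 0.11 over 39 genes, led by TAP1, XAF1, GBP5 and PARP12. Each of these 3 lists had 4 genes at an unadjusted p under 0.05, all higher in MIX, and 0 genes when adjusted over the list alone. The number expected by chance was 1.9 for T and NK cells, 1.2 for antigen presentation and 2 for interferon-stimulated genes.

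The camera test with its preset correlation called these 3 lists with adjusted p-values of 2.73e-04, 0.00233 and 0.00217, against 0.571 for each with an estimated correlation. The interferon list rested on MIX 9, whose mean of 0.53 log2 lay above all other samples: without it the median was -0.004 and the adjusted p 0.863, and the median was 0.06 without ISe 2, 0.20 without ISe 7 and 0.23 without MIX 1 and MIX 8. The antigen presentation list had a median of 0.07 and an adjusted p of 0.13 without MIX 10, and medians of 0.06 without MIX 8, 0.17 without ISe 3, 0.165 without MIX 1 and 0.22 without the dimmer 50% of probesets, while T and NK cell markers had 0.11 without MIX 10. Markers of B and plasma cells (17 genes) and of neutrophils and eosinophils (20 genes) were not called, with medians of 0.002 and -0.002 and adjusted p-values of 0.912 and 0.934. In the same samples the mean of the macrophage list was 0.32 log2 higher in MIX.

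Genes of cholesterol synthesis, which supplies the substrate of progesterone, were higher in MIX by small amounts (adjusted p = 7.62e-08 by camera with its preset correlation, adjusted p = 0.347 with an estimated correlation). Of the 19 measured, 18 had a higher mean in MIX, with a median difference of 0.13 log2, and 8 had an unadjusted p under 0.05, all higher in MIX. TM7SF2, a sterol reductase, was at 9.73 ± 0.29 in MIX and 9.31 ± 0.14 in ISe (SD, n = 5 each), 1.34-fold. FDFT1, squalene synthase, was 1.21-fold, CYP51A1, lanosterol demethylase, 1.17-fold and SQLE, squalene epoxidase, 1.15-fold higher, whereas HSD17B7 was at -0.12 ± 0.10 (log2 difference ± SE). No gene passed when adjusted over the list alone, where the smallest adjusted p was 0.0893, or over all probesets.

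An exact permutation test of the cholesterol synthesis list means gave p = 0.0238 and an adjusted p of 0.246, where the adjusted test could hardly call a list. The list means lay farthest from 0 in ISe 5 at -0.236, MIX 8 at 0.168 and MIX 1 at 0.102. The groups overlapped, with ISe 2 at 0.023 above MIX 9 at 0.018 and MIX 10 at 0.021. The 8 genes became 4 without ISe 5 or without MIX 8, and 1 without MIX 1 and MIX 8 together. In the same samples the macrophage list mean was 0.32 log2 higher in MIX.

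**Figure D2:**
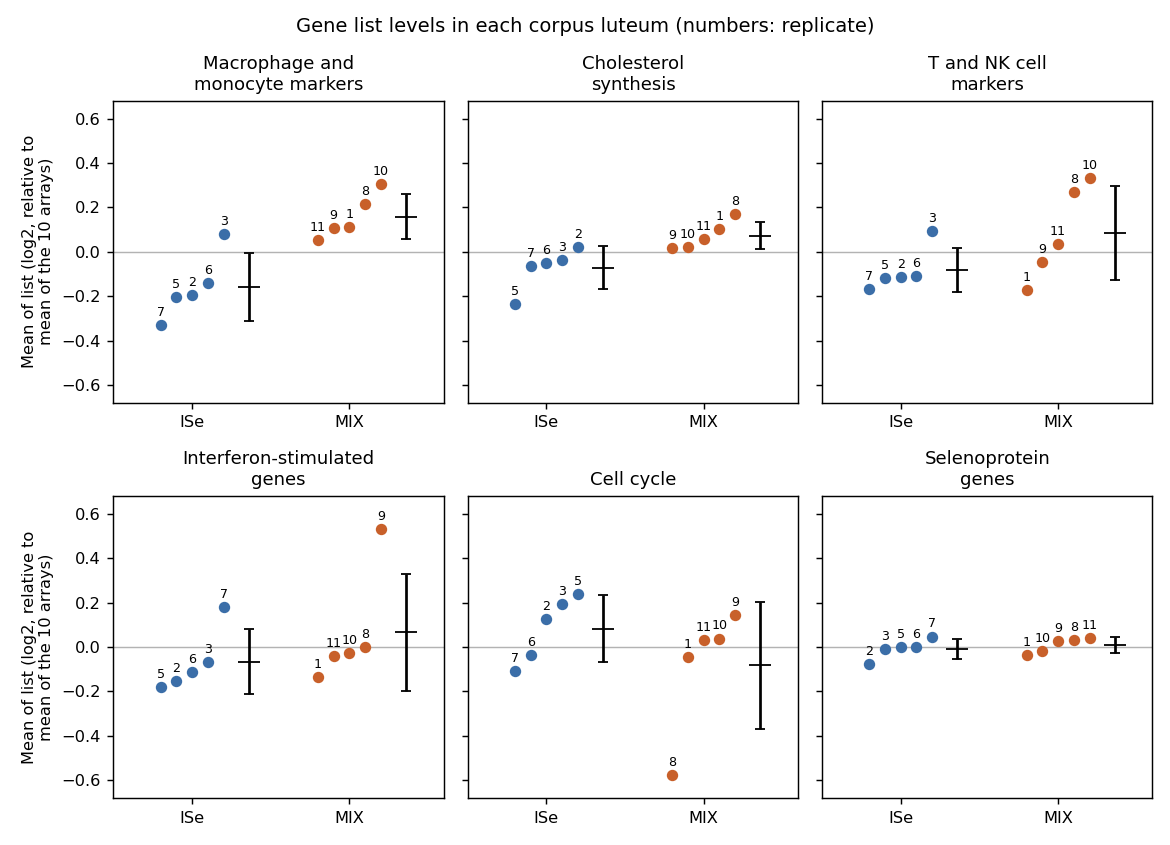
Mean of each gene list in each corpus luteum, in log2 units relative to the mean of the 10 arrays (vertical axis), for 6 lists and both groups, with replicate numbers beside the points and black marks for the group mean ± SD of 5 arrays. Macrophage markers lie between 0.06 and 0.30 in MIX and between -0.33 and 0.08 in ISe, and single arrays stand apart for the interferon list (MIX 9 at 0.53) and the cell cycle list (MIX 8 at -0.58).

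A list of adipocyte markers was not called as a whole, with 9 of its 18 genes above ISe and 9 below. Of these genes, FASN (fatty acid synthase, 1.34-fold), LIPE (hormone-sensitive lipase, 1.21-fold) and LPL (lipoprotein lipase, 1.83-fold) were higher in MIX when adjusted over the list alone, with adjusted p-values of 0.0141, 0.0142 and 0.0255, and 0 passed over all probesets. That adjustment does not account for the 31 lists examined. ACACA, acetyl-CoA carboxylase, was at 0.22 ± 0.08, PLIN1, the coat protein of fat cell droplets, at -0.19 ± 0.07 and ADIPOQ, the hormone adiponectin, at -0.03 ± 0.13 (log2 difference ± SE). PLIN1 averaged 5.12 in MIX and 5.31 in ISe, and ADIPOQ 4.51 and 4.54. Both lay below the array medians near 6.0, so their differences are less certain and say little about fat cells in the samples. The list had a median of 0.04 and a camera adjusted p of 0.0574 (adjusted p = 0.493 with an estimated correlation), and the 3 genes became 0 without MIX 1 and MIX 8 together. It was called without the dimmer 50% of probesets (median 0.20, adjusted p = 6.99e-06), without the dimmest 25% (0.019), and without MIX 1 (0.0303), ISe 3 (0.0336), ISe 5 (0.039), MIX 9 (0.0425) or MIX 11 (0.044). With 1 array left out its median ran from 0.005 without MIX 10 to 0.081 without MIX 11. The macrophage list mean was 0.32 log2 higher in MIX in the same samples. Cholesterol uptake, storage and efflux genes (26) had a median of 0.02 (camera adjusted p = 0.432) with 1 gene, LIPE, past the threshold when adjusted over the list alone, beside NPC2 at 0.28 ± 0.09, LIPA at 0.33 ± 0.14 and PLIN2 at -0.26 ± 0.14. In the mixed test of fry, which asks whether a list's genes change in either direction, the macrophage, adipocyte and cholesterol uptake lists had an adjusted p of 0.0153, while its directional test called 0 of the 31 lists (smallest adjusted p = 0.157).

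Genes of steroid hormone synthesis did not differ past the threshold, alone or as a list. CYP11A1, which cleaves the side chain of cholesterol, was at 12.99 ± 0.03 in MIX and 13.01 ± 0.04 in ISe, and HSD3B1, which makes progesterone, at 13.34 ± 0.02 and 13.33 ± 0.02 (SD, n = 5 each). The 95% intervals of the fold change were 0.92 to 1.06 for CYP11A1, 0.94 to 1.08 for HSD3B1 and 0.94 to 1.12 for SCARB1, the receptor for high-density lipoprotein. These 3 genes lie near the top of the arrays, whose highest values were 14.09 to 14.17 and where array signals are compressed, so their narrow intervals bound a change in transcript less firmly than those of other genes. The intervals were wider for 2 genes with more spread between samples. They were 0.68 to 1.15 for LHCGR, the receptor for luteinizing hormone (SD 0.31 in MIX and 0.30 in ISe), and 0.68 to 1.02 for NR5A1, a transcription factor of steroidogenic cells (SD 0.19 in MIX and 0.27 in ISe). Of the 35 genes measured, POR (0.15 ± 0.05, log2 difference ± SE) and HSD17B1 (-0.25 ± 0.09) had an unadjusted p under 0.05 and GATA4 (-0.13 ± 0.06) did not, 0 passed when adjusted over the list alone, and the list had a median of -0.01 (camera adjusted p = 0.567), or 0.008 without ISe 2. STAR was not analysed here because no probeset named it alone.

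None of the 25 selenoprotein genes, whose products carry selenium as selenocysteine, differed between the 2 forms of selenium past the threshold. Their log2 differences ran from -0.10 (SELENOW) to 0.14 (MSRB1 and DIO1), with a median of 0.01, 0 genes at an unadjusted p under 0.05, 0 called by limma over the list alone or over all probesets, and a camera adjusted p of 0.659. GPX4, the glutathione peroxidase that acts on membrane lipids, had a fold change of 1.01 (95% interval 0.92 to 1.11), TXNRD1, cytosolic thioredoxin reductase, 1.03 (0.89 to 1.18) and SELENOP, the selenium transport protein of plasma, 1.04 (0.84 to 1.29). For 18 of the 25 the interval lay inside 0.8-fold to 1.25-fold, and the bounds over all of them reached 0.68 and 1.39. The 18 include DIO2, DIO3 and SELENOV, whose means lay under 5 on the log2 scale, where a narrow interval bounds a change in transcript less firmly. The widest spread was that of GPX1, the cytosolic glutathione peroxidase, at 11.41 ± 0.51 in MIX and 11.48 ± 0.20 in ISe (SD, n = 5 each). Without MIX 1 and MIX 8, at 10.73 and 11.01, its log2 difference changed from -0.08 to 0.28 and stayed short of the threshold.

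The other selenoprotein genes measured were GPX2, GPX3, GPX6, TXNRD2, TXNRD3, DIO2, DIO3, SELENOF, SELENOH, SELENOI (0.10 ± 0.05, log2 difference ± SE, the groups not overlapping), SELENOK, SELENOM, SELENON, SELENOO, SELENOS, SELENOT, SELENOV and SEPHS2. Of the 25, 6 had an ISe mean under 5 on the log2 scale, below the median array level. The genes of selenium handling and selenocysteine insertion (19) had a median of -0.003 and an adjusted p of 0.934, and antioxidant genes (40) a median of -0.02 and an adjusted p of 0.374, with MGST2 at -0.20 ± 0.09, GSTA1 at -0.16 ± 0.08, SOD3 at 0.25 ± 0.12 and ABCC1 at 0.26 ± 0.10 (log2 difference ± SE).

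**Figure D3:**
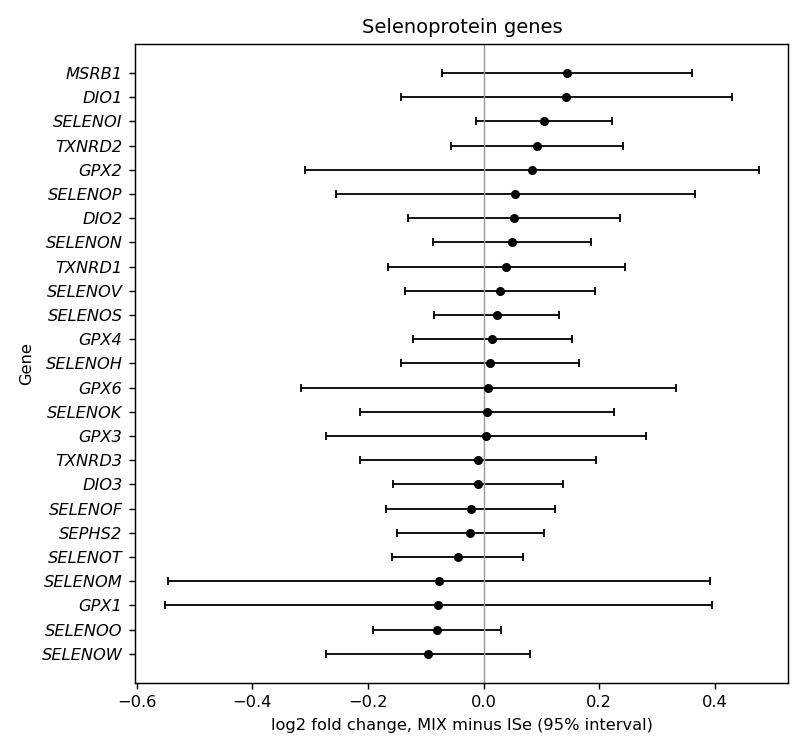
Log2 fold change of MIX over ISe (horizontal axis) for the 25 selenoprotein genes measured (vertical axis), with points for the estimate from 5 arrays per group and bars for the 95% interval. All estimates lie between -0.10 and 0.14, and every interval crosses 0.

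Cell cycle genes were lower in MIX, with most of the difference in a single sample, MIX 8 (camera adjusted p = 2.90e-08, adjusted p = 0.571 with an estimated correlation). Of 46 genes, 45 had a lower mean in MIX (RRM1 at 0.03 ± 0.10 was the exception), with a median of -0.16 log2 and 1 gene, the mitotic cyclin CCNB1 (-0.21 ± 0.09, log2 difference ± SE), at an unadjusted p under 0.05. BIRC5 was at -0.28 ± 0.15, PRC1 at -0.30 ± 0.16 and CDT1 at -0.16 ± 0.09, and 0 genes passed over the list alone. Without MIX 8, whose list mean was -0.58, the median was -0.04 and the adjusted p 0.133, and with array quality weights the median was -0.09.

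Genes of the respiratory chain (41) and of ribosomal proteins (41) were lower in MIX, each with a median of -0.05 log2, and 34 and 35 members lay below ISe (camera adjusted p = 0.00386 and 0.00639, each with adjusted p = 0.571 with an estimated correlation). The mean over the ribosomal genes was only -0.011, with an exact permutation p of 0.802 (adjusted 1). NDUFV2, of complex I, was at -0.14 ± 0.06 and the only respiratory gene at an unadjusted p under 0.05, with UQCRC1, ATP5PB and ATP5PF next. Among ribosomal genes the smallest p-values went the other way, with RPL15 at 1.25 ± 0.36 (1.63 without MIX 8, where it passed over all probesets with an adjusted p of 0.0241) and RPL26L1 at 0.39 ± 0.12, followed by RPS12 and RPL22L1 at -0.19 ± 0.09 and -0.21 ± 0.10 (log2 difference ± SE). The respiratory call ended without MIX 1 (median -0.022, adjusted p = 0.113), ISe 2 (-0.022, 0.283) or MIX 8 (-0.030, 0.113) or with array quality weights (-0.019, 0.207), and the median was -0.076 without ISe 6. The ribosomal call ended without ISe 3 (-0.033, 0.0628) or MIX 8 (-0.022, 0.374), after quantile normalisation (-0.038, 0.0603) or with array quality weights (-0.029, 0.115), and the median was -0.031 without MIX 1. Without MIX 1 and MIX 8 together the adjusted p-values were 0.897 and 0.796.

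Endothelial markers were higher in MIX, with 31 of 35 above ISe and a median of 0.11 log2 (camera adjusted p = 1.15e-04, adjusted p = 0.571 with an estimated correlation). TEK, the angiopoietin receptor, was at 0.16 ± 0.07, CALCRL, a receptor of adrenomedullin, at 0.22 ± 0.10, FLT1, a receptor of vascular endothelial growth factor, at 0.23 ± 0.11 and MMRN1 at 0.75 ± 0.36 (log2 difference ± SE). Angiogenesis genes had a median of 0.07 over 34 genes (camera adjusted p = 0.0157, adjusted p = 0.347 with an estimated correlation), with TEK, FLT1, MET and HGF at the smallest p-values. In these lists 2 genes and 1 gene had an unadjusted p under 0.05, against 1.8 and 1.7 expected by chance, and 0 passed over the list alone. The angiogenesis call ended without MIX 1 (adjusted p = 0.0619), ISe 3 (0.0579) or MIX 10 (0.13), its median was 0.11 without MIX 9, and the endothelial median was 0.07 without MIX 10. Without MIX 1 and MIX 8 together the angiogenesis list had an adjusted p of 0.219. The macrophage list mean was 0.32 log2 higher in MIX in the same samples.

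Single genes with the smallest unadjusted p-values, none past the adjusted threshold, were FCGR1A, EPB41L3, SLCO2B1, ARRB2, SLAMF7, SLC39A1, INPP5D, FASN, CD68 and CD14 among those higher in MIX. EPB41L3 had a fold change of 1.40 (95% interval 1.22 to 1.59), SLCO2B1, an organic anion transporter, 1.39 (1.21 to 1.59), and SLC39A1, a zinc transporter, 1.28 (1.14 to 1.42). Those lower in MIX were CFAP300, MRPS15, OR6C3, ADAM22, TMA7, INFAF, CRIPTO, TNNT3, PTN and OR2H1D. Of the latter, CRIPTO, OR2H1D, INFAF, ADAM22 and TNNT3 had group means from 2.94 (CRIPTO in MIX) to 5.03 (TNNT3 in ISe). SLAMF7, among those higher, averaged 5.37 in MIX and 4.92 in ISe. All of these lay below the array medians near 6.0, so their differences are less certain. PTN, the growth factor pleiotrophin, averaged 9.51 ± 0.34 in MIX and 10.18 ± 0.25 in ISe (SD, n = 5 each), and MRPS15, a mitochondrial ribosomal protein, 7.93 ± 0.07 and 8.21 ± 0.08. The groups did not overlap for 123 probesets, against 151.9 expected at the 0.794% that chance gives.

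Markers of the other cell types and pathways were not called. Fibroblast and matrix genes (38) had a median of -0.02 with an adjusted p of 0.659, pericyte and smooth muscle genes (22) -0.02 with 0.818, granulosa genes (24) -0.07 with 0.12, and theca and small luteal cell genes (15) -0.02 with 0.458. Peptides and prostaglandin enzymes of large luteal cells (29) had a median of 0.01 with an adjusted p of 0.432, erythroid genes (12) -0.02 with 0.743, and oocyte and surface epithelium genes (19) -0.03 with 0.48. Among pathways, apoptosis (25) had a median of 0.02 with 0.12, immediate early genes (33) -0.07 with 0.0871, heat shock genes (18) -0.01 with 0.934, and genes of the stress response of the endoplasmic reticulum (29) -0.02 with 0.719. Genes of the citric acid cycle and fatty acid oxidation (35) had a median of -0.02 with 0.432, and those of glycolysis and glucose uptake (27) 0.04 with 0.523. Leaving out 1 array brought some of these lists past the threshold: granulosa genes without ISe 5 (adjusted p = 0.0444), ISe 6 (0.0334) or MIX 9 (0.0153), immediate early genes without ISe 5 (0.00148) or MIX 10 (6.99e-04), fibroblast genes without ISe 2 (0.0477), and apoptosis genes without ISe 2 (0.0458) or MIX 11 (0.0353). The median and the mean differed in sign for the fibroblast, pericyte, B cell and neutrophil lists, and the median and the camera direction for the B cell, neutrophil and selenium handling lists.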

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

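The tests of the probeset counts over other splits of the arrays were set before their results were seen, and every test of a gene list in this part was chosen after the list's result was seen.

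Macrophage and monocyte markers were higher in MIX (adjusted p = 0.263 with an estimated correlation), and the values argue against a single array, since leaving out any array kept the median at 0.26 or more. A smaller share of luteal cells would raise markers of the other cell types alike. The macrophage list was 0.309 log2 higher relative to fibroblast and pericyte markers (SE 0.061, exact p = 0.00794, the smallest possible). It was 0.27 higher with endothelial markers added to these (SE 0.061, exact p = 0.00794). These comparisons were chosen when the fibroblast and pericyte means were known to differ by only 0.004 and 0.011, so their p-values largely restate the macrophage difference. Endothelial and T and NK cell markers were themselves higher in MIX (each adjusted p = 0.571 with an estimated correlation). The difference from endothelial markers alone was 0.191 (SE 0.093, exact p = 0.0794), so these values do not settle whether the share of luteal cells played a part. More blood in the MIX pieces cannot be told apart, because although the macrophage list was 0.322 higher relative to erythroid genes, the most abundant of these measured, HBQ1 at 6.13 and HBG at 5.23, lay below the median level of 6.40. As small a camera p for this list arose in 2 of 100 splits of the arrays (-log10 p of 19.15 against a highest other of 20.51), but some list reached as small a p in 7 of 100 (highest other 26.8), so chance cannot be excluded for the smallest p over all 31 lists. Of the 32 markers, 1 (CTSS) is in another list and 16 lie above the median level, and the form of selenium stays open as a biological explanation, as do more macrophages or more transcript per macrophage, none of which was tested.

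Cholesterol synthesis genes were higher in MIX (adjusted p = 0.347 with an estimated correlation), and neither a trend with signal level nor a single array accounts for the whole difference. In 10000 random lists matched on level the medians centred on -0.009 (SD 0.021), and 0% reached 0.13. The genes of those lists were drawn without regard to relation, whereas this list had an estimated correlation of 0.279. The 0% thus speaks to a trend with level and not to chance. Leaving out ISe 5, the array whose absence lowered it most, left a median of 0.087, and the camera call held without any single array, though not with an estimated correlation (adjusted p = 0.347). As small a camera p for this list arose in 2 of 100 splits (-log10 p of 8.132 against a highest other of 8.439). Chance is thus unusual for this list taken alone but cannot be excluded, since the list was picked among 31 for its small p. The exact permutation of its means had an adjusted p of 0.246, from a test that could hardly call a list. The form of selenium stays open and was not tested.

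Cell cycle genes were lower in MIX, and the values are consistent with a single array as the source: without MIX 8 the median was -0.04 in place of -0.16, and the camera call ended, as it did with an estimated correlation (adjusted p = 0.571). In 31 of 100 splits the list had as small a camera p (-log10 p of 8.728 against a highest other of 26.8), so chance cannot be excluded. MIX 8 lay at -0.58 on this list, below the other MIX samples at -0.045 or more. What sets MIX 8 apart was not tested.

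Over 100 splits of the arrays, 36 gave as many as the 918 probesets at an unadjusted p under 0.05 (highest other 1418). As many as 10 called lists arose in 12 splits (highest other 13), and the median over splits was 6 called lists. Chance thus cannot be excluded for these counts. All 100 necessarily gave as many as the 0 adjusted calls (highest other 2), which says nothing about chance. As small a camera p arose in 15 splits for endothelial markers, 22 for T and NK cell markers, 39 for interferon-stimulated genes, 14 for antigen presentation, 26 for the respiratory chain and 23 for ribosomal proteins, so chance cannot be excluded for these 6 lists, whose real -log10 p of 4.829, 4.357, 3.377, 3.279, 3.001 and 2.732 had highest others of 14.38, 10.29, 10.46, 8.433, 8.822 and 8.108. For angiogenesis it arose in 3 splits (2.296 against a highest other of 3.325), but the list was picked among 31 for its call and the exact permutation of its means gave p = 0.135, so chance cannot be excluded.

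A sample lay far from the other 4 of its group in 25 of 302 groups of values examined, against a nominal 15.1. Most of these groups of values are those of the named genes, many chosen for small p-values or after their values were seen. Many also vary together, so the nominal count is not a firm measure of chance, and an excess over it was not tested. MIX 8 lay apart on the first principal component at 32.8, and was lowest for PRC1 at 7.21, BIRC5 at 6.04, TXNRD1 at 8.01 and RPL15 at 7.38, and highest for PLIN1 at 5.36. MIX 9 was highest for the interferon list at 0.53, PTN at 10.11 and DIO1 at 3.81. MIX 11 was lowest for selenium handling genes at -0.06 and ADIPOQ at 4.0, and highest for MET at 6.86 and FABP3 at 12.48, and MIX 10 was lowest for SELENOT at 10.05. ISe 5 was lowest for CYP51A1 at 10.77, SQLE at 11.26, SCD at 12.61 and GPX6 at 3.61, and highest for BOLA at 9.48. ISe 7 was highest for SLC39A1 at 7.88, SELENOF at 11.69 and SEPHS2 at 7.86, ISe 6 for SELENOO at 6.93, and ISe 3 for T and NK cell markers at 0.09.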

How the results depend on the processing

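Leaving out MIX 1 and MIX 8 together, the exact permutation of list means, and the counts of genes within lists were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers.

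The count of adjusted calls was 0 under all settings with all arrays, and 0 to 1 when 1 array was left out, the 1 being RPL15 without MIX 8 (log2 difference 1.63, adjusted p = 0.0241). Unadjusted counts were 548 without the dimmer 50% of probesets, where fewer are tested, 716 to 1288 under the other settings with all arrays and 769 to 1050 with 1 array left out. The exact p of the group distance ran from 0.111 to 0.659 with 1 array left out. Called lists numbered 7 to 13 with 1 array left out, 6 without MIX 1 and MIX 8, 0 with an estimated correlation and 0 by exact permutation of list means, against 10. The 0 by exact permutation says little, because a single list at the smallest possible exact p would not pass the adjustment over the lists.

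The macrophage list had a median of 0.503 without the dimmer 50% of probesets, where fewer markers are tested, a difference of 0.308 (adjusted p = 0.263) with an estimated correlation and 0.317 (0.246) by exact permutation, and the cholesterol synthesis list 0.129 (0.347) and 0.146 (0.246). The cell cycle list had -0.162 (0.571) and -0.165 (0.688), -0.227 to -0.04 with 1 array left out, and -0.012 without MIX 1 and MIX 8. Macrophage markers adjusted over the list alone numbered 8 without moderation, 3 without MIX 1 and MIX 8, and 7 to 15 with 1 array left out. Cholesterol synthesis genes at an unadjusted p under 0.05 numbered 1 without MIX 1 and MIX 8 and 4 to 8 with 1 array left out.

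Of 708 values of lists under other settings, 38 lost the call and 15 gained it. The sign differed in 52 of the 708, spread over 15 lists, and in 58 of 2293 values of the 117 named genes, spread over 19 genes. Of these values, 1 belongs to a called list (interferon without MIX 9) and 0 passed the limma or camera threshold. Signs turned with a shift of more than 1 standard error, and with no call on either side, for the cholesterol uptake list (-0.012 to 0.036 with 1 array left out, -0.001 without MIX 8, -0.012 without MIX 10, -0.011 without MIX 1 and MIX 8), the granulosa list (0.016 without MIX 1 and MIX 8), the large luteal cell list (-0.011 without MIX 9, up to 0.038) and selenium handling (0.018 without MIX 11, down to -0.019). Without MIX 1 and MIX 8 they also turned for GPX1 (0.282), GPX6 (-0.170), SELENOM (0.185), SELENON (-0.023) and SELENOP (-0.169). Except where fewer arrays or probesets explain it, the cause was not tested. Signal over background was not given, so genes of low level are the least certain.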

Other observations

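The correlations between list means and the genes singled out in this part were chosen after the results were seen, and the test of the replicate numbers was set before its result was seen.

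Among apoptosis genes, 3 of 25 had an unadjusted p under 0.05, against 1.2 expected by chance. All 3 were higher in MIX: TNFSF10, a death ligand, at 0.26 ± 0.07, BIRC3, an inhibitor of apoptosis, at 0.23 ± 0.07 and FAS, a death receptor, at 0.35 ± 0.15 (log2 difference ± SE). DIABLO, which releases caspases from inhibition, was at -0.12 ± 0.06. No gene passed when adjusted over the list alone (smallest adjusted p = 0.0685), and the camera adjusted p of the list was 0.12. Beside FASN, LIPE and LPL, FABP3, a fatty acid carrier, was 1.35-fold higher in MIX, at 12.28 ± 0.12 against 11.84 ± 0.21 (SD, n = 5 each), with no overlap between the groups and an adjusted p of 0.926. SCD, the fatty acid desaturase, had a fold change of 1.06.

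Differences of more than 1 log2 were found for 9 probesets, 5 higher and 4 lower in MIX, and none passed the adjusted threshold with all 10 arrays. GNLY, a granule protein of cytotoxic lymphocytes, ran from 1.78 to 5.97 in ISe and from 2.96 to 7.71 in MIX. RPL15 lay at 9.04 to 9.52 in 4 MIX samples and at 7.38 to 8.13 in MIX 8 and the ISe samples. BOLA, a class I histocompatibility gene, lay at 8.57 to 9.65 in 4 MIX samples and ISe 5, which had 9.48, and at 6.73 to 7.09 in MIX 8 and the other ISe samples. GSDME was at -1.17 ± 0.36, NPS at -1.49 ± 0.72, CSRP3 at -1.04 ± 0.48, IFI47 at 1.15 ± 0.52 and LRRN3 at 1.04 ± 0.48 (log2 difference ± SE). Among the 7628 probesets with no gene symbol, limma called 0 at an adjusted p under 0.05 (smallest 0.928), with 372 at an unadjusted p under 0.05 against 381.4 expected.

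Over the 10 arrays the macrophage and cholesterol synthesis means correlated at r = 0.63 (permutation p = 0.0426, adjusted 0.0977) and rho = 0.67 (p = 0.0393, adjusted 0.118), among 3 relations computed. Without ISe 7 and ISe 5, the arrays farthest from the median macrophage mean, r was 0.46, and within the groups it was 0.15. With 10 arrays these values do not settle whether the relation goes beyond the difference between the groups. The cholesterol synthesis and cell cycle means had r = -0.66 (adjusted 0.0977), which was 0.05 without ISe 5 and MIX 8 and rests on those samples. The macrophage and cell cycle means had r = -0.28.

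The replicate numbers run from 2 to 7 in ISe and are 1 and 8 to 11 in MIX, so that an order of processing by number and the group cannot be told apart except through MIX 1. On the probesets with an unadjusted p under 0.05 between the other arrays, MIX 1 lay at 0.391 on a scale from 0 at ISe to 1 at MIX. The other MIX arrays left out in the same way lay at 0.307 to 0.457 and the ISe arrays at 0.405 to 0.644, so this test did not separate the groups and leaves the question open.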
